A study of Mus musculus with 11 samples.

How the data were processed

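Small RNA was measured in 11 mouse libraries, 1 for each of 11 stages: uninduced Mbd3f/- MEF, days 1 to 8 after doxycycline, an established iPSC line and an ESC line. Per the labels' protocols, reprogramming began in serum with LIF at low oxygen, and the medium was changed during the course to serum replacement with LIF and inhibitors of MEK and GSK3. The sources differ on the day on which the inhibitors were added. Per the labels, cells of MEF and days 1 and 2 grew without feeders and those of days 3 to 8, iPSC and ESC on irradiated human foreskin fibroblasts, so the feeders, the medium and the later days cannot be separated by design. Libraries were made with the TruSeq small RNA kit, with size selection on a gel, per the labels. The wild-type and Gatad2a-deficient lines that the series also describes were not analysed here.

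The deposited table gives FPKM, fragments scaled to transcript length and to the library's mapped fragments, computed by the authors for small RNA genes in 11 columns, with 0 columns of other samples. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2, Cufflinks 2.2.1 and the genome build mm10, without roles. The annotation the authors used, how reads that match several loci were shared and how the table was filtered are not given in the sources used here. Gene IDs were looked up in GENCODE vM21 (GRCm38), where 3712 of 3859 were found and 147 were not. Coordinates are from that annotation, and 55 names were shared by several IDs. FPKM of a gene shorter than the assumed fragments depends strongly on its length, so values were compared between libraries within a transcript and less safely between transcripts. The 268 positive values below 0.001 FPKM were kept.

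Depth was recovered from the steps of the low values. The relative depths were taken from values below 200 FPKM. The worth of 1 read was corrected for transcript length with an assumed Gaussian fragment length of 200 ± 80 nt. For 324 of 325 low transcripts with a step, it then lay within 10% of the median of these transcripts. Of 4813 values between 0.5 and 5.5 reads, 91.7% were whole within 0.05 read, where chance gives 10%. The worth of 1 read had been set on transcripts whose low values were whole multiples. Those values were not held out, so the share of whole values is not an independent check. The implied mapped reads were 11600000 in MEF, 12500000, 13700000, 19600000, 18300000, 12600000, 14700000, 21900000 and 20600000 on days 1 to 8, 14900000 in iPSC and 17800000 in ESC. They rest on that model. For a transcript of 80 nt, 1 read was worth 26.4 FPKM on day 7 and 49.8 in MEF, and on day 3 it was worth 52.8 at 65 nt and 12.4 at 107 nt. FPKM values below about 50 in a short transcript are therefore near the level of 1 read. Because the worth of a read depends on transcript length through an assumed model, no count test was run.

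A value of 0 in an abundant transcript was listed apart when the nearest library with a value held at least 10000 reads, or when the transcript lay within 10 kb of such a transcript and the nearest library held at least 100 reads. This rule was set after the zeros were seen. It covered 25 values in 15 transcripts, for which no fold is given, and which were left out of list medians between single stages.

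Values were analysed as log2(FPKM + 10) over the 1419 transcripts with a mean FPKM of at least 10, 901 of them miRNAs. A difference on this scale understates the change of low transcripts. Over 9 libraries, with MEF placed at day 0, limma 3.58.1 in R 4.3.3 gave the slope per day (two-sided, empirical Bayes, 7 residual and 2.53 prior degrees of freedom, prior SD 0.877) and an F-test of day and day squared, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of slopes are standard errors over those 9 libraries, and every adjusted p of a transcript is limma's. MEF is not a treated day, and the slope includes the step from MEF to day 1. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and adjusted over 21 lists.

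The lists were fixed before the data were examined, as were the design and all other settings but those named below as chosen later. They were the miR-290, miR-302, miR-17-92, miR-183-96-182, miR-322 and miR-99-100-125 clusters, the miR-200 family with miR-203 and miR-205, the let-7, miR-29 and miR-34 families, Hox cluster, Dlk1-Dio3 and Sfmbt2 intron miRNAs, C/D box, H/ACA box and Prader-Willi locus snoRNAs, and Cajal body RNAs. Lists of cell types were the fibroblast and mesenchymal, muscle, blood cell, endothelial and neural miRNAs. The end points and the lines were compared without a test, counting transcripts at least 4-fold apart, in both lines for the comparison with MEF. List medians were set against 10000 random lists of the same size matched on mean expression by decile. Transcripts of these random lists were drawn singly, without regard to clusters. The position of a library is its projection on the axis from MEF to the mean of iPSC and ESC, with 95% intervals from 500 bootstrap draws of transcripts. Steps between consecutive stages counted transcripts at least 2-fold apart.

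The rule for named transcripts was also fixed then. It took the 10 steepest rising and 10 steepest falling transcripts, the 5 with the largest fitted range among those that changed without a linear trend, and the 4 members of each list with the highest mean FPKM, with any member of a cluster of up to 12 that is counted singly. It also took the 10 highest and 10 lowest in the lines against MEF, the 5 highest and 5 lowest between the lines and the 5 with the highest mean. Mir106a, Mir20b, Mir363, Snora33, Snord73a, Mir675, Gm25802 and the X-linked cluster were chosen after their values were seen, as were Mir17, Mir18, Mir19a, Mir19b-1, Mir20a and Mir433, which were named for values listed at 0.

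Other settings tried were pseudocounts of 1 and 100, rescaling by median ratios, quantile normalization, no filter and a mean of at least 100, leaving out each library, days 3 to 8 alone, miRNA transcripts alone, other error models in limma, an exact Spearman permutation test over 362880 orders, an estimated correlation, fry, a miRNA background and other size rules. Treating the zeros of abundant transcripts as missing, leaving out days 7 and 8 and scaling to recovered miRNA reads were chosen after seeing the data. The linear test was tested on simulated data with 200 of 1419 transcripts changed over 9 libraries. It recovered 14.7% at a slope of 0.25, 60.6% at 0.5 and 93.9% at 1. Of all its calls, 4.3% were unchanged transcripts. With a shift simulated in the miR-302 list alone, camera called that list and 0 of the others among the 21. The simulated scatter was independent between transcripts, so this cannot show false calls of lists whose members move together. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.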

Results

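Small RNA was sequenced from mouse cells on their way from embryonic fibroblasts (MEF) to induced pluripotent stem cells (iPSC). The cells were labelled Mbd3f/-, with 1 floxed and 1 deleted allele of Mbd3, a subunit of the NuRD chromatin remodelling complex. They carried a doxycycline-inducible cassette for the reprogramming factors Oct4, Klf4, Sox2 and Myc (OKSM). The 11 libraries were 1 each of uninduced MEF, days 1 to 8 after doxycycline, an established iPSC line and an embryonic stem cell (ESC) line. The ESC library is labelled Mbd3f/-, but its column in the table carries the name V6.5, so its genotype is unclear. Each stage had 1 library, so a p-value over the course measures the scatter of these 9 libraries around a trend and not the spread between cultures. Per the labels, the libraries of days 3 to 8, iPSC and ESC came from cells on irradiated human foreskin fibroblasts.

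The table held FPKM for 3859 small RNA genes, of which 1739 were listed at 0 in every library and 787 were above 0 in every library. The value of 1 read implied about 11600000 mapped reads in the MEF library and up to 21900000 on day 7. The table took 48.7% of the implied mapped reads in MEF, 58.9% on day 1 and 44.7% on day 6, but 22.6% on day 7 and 27.5% on day 8. It took 53.6% in iPSC and 51.3% in ESC. Of the reads in the table, miRNA genes took 98.4% in MEF, between 90.8% and 96.0% on days 1 to 8, 89.7% in iPSC and 90.5% in ESC. The snoRNA share was 1.21% in MEF, 5.73% on day 1 and 9.81% in iPSC. The 5 transcripts with the highest mean were Mir183, Mir10b, Mir92-1, Mir143 and Mir295.

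**Figure D1:**
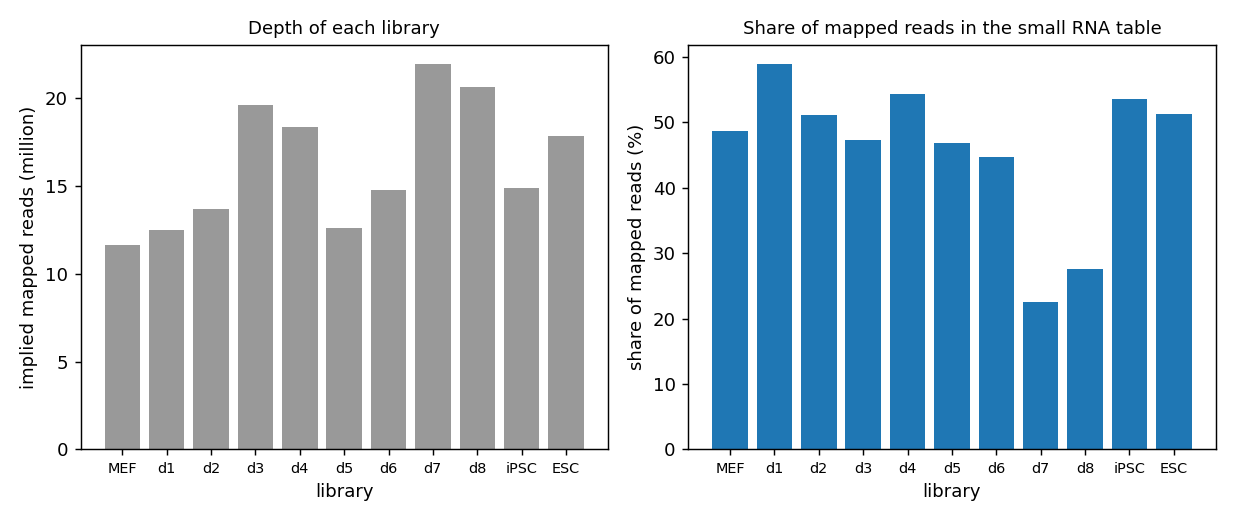
Implied mapped reads (left) and the share of them in the small RNA table in percent (right) for each of the 11 libraries (MEF, d1 to d8 for days 1 to 8, iPSC and ESC), 1 bar per library. Day 7 had the most mapped reads, 21900000, and the lowest share in the table, 22.6%.

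In 15 abundant transcripts, 25 values were listed at 0 in single libraries while the nearest library with a value held 3497 reads or more. Mir143 and Mir10a were listed at 0 in MEF. Mir127, Mir136, Mir431, Mir433 and Mir434 were listed at 0 in MEF and on day 4. Mir17, Mir18, Mir19a, Mir20a, Mir19b-1 and Mir92-1 were listed at 0 on day 2. Mir182 was listed at 0 on days 6 to 8 and in both pluripotent lines, and Mir295 in both pluripotent lines. No fold is given against these values.

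The first comparison asked which small RNAs moved with time over the course from MEF to day 8. All tested members of the miR-290 and miR-302 clusters, known from pluripotent cells, rose, and all 6 muscle miRNAs fell. Most tested members of the fibroblast, let-7 and miR-99-100-125 lists fell too. Of 1419 transcripts tested with limma, 177 rose and 150 fell at a Benjamini-Hochberg adjusted p under 0.05, and 1092 did neither. The rising transcripts were 105 miRNAs and 72 others, and the falling ones were 146 miRNAs and 4 others. In the miRNA transcripts tested alone, 111 rose and 158 fell, and with reads scaled to the recovered miRNA reads of each library 171 rose and 109 fell. Without the MEF library 93 rose, without day 1 110 and without day 6 114. Without day 7 97 fell and without day 8 98. Without both days 7 and 8, whose share of reads in the table was lowest, 181 rose and 69 fell. Of the 150 that fell, 66 kept the call in that fit. In every fit that left out 1 library, 64 of the 177 and 81 of the 150 kept theirs.

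The steepest rises belonged to 2 transcripts of the imprinted Dlk1-Dio3 region on chromosome 12, followed by miRNAs of the X chromosome and of the pluripotency clusters. Mir654 rose by 1.44 ± 0.38 per day (log2, SE; limma adjusted p = 0.0253) and the snoRNA Gm24899 by 1.42 ± 0.37 (adjusted p = 0.023). Both changed in 1 step: Mir654 was at 147 FPKM on day 2 and 297835 on day 3, and Gm24899 was listed at 0 through day 2 and at 29241 on day 3. Day 3 was the first stage labelled as on human feeder cells, which the design does not separate from the later days. In the iPSC line Mir654 and Gm24899 were at 67.5 and 50.4 FPKM, and in ESC at 164921 and 14177. Within days 3 to 8 their slopes were -0.27 and -0.15. The adjusted p of Mir654 was 0.0982 without MEF, 0.0765 without day 1 and 0.0528 without day 6. That of Gm24899 was 0.0839 without MEF and 0.072 without day 1. The X-linked Mir881, Mir465b-1, Mir471 and Mir465c-1 rose by 1.33, 1.27, 1.21 and 1.21 per day. All 4 were listed at 0 in MEF and stood between 4202 and 13239 FPKM on day 8. Mir465b-1 and Mir465c-1 are near-identical copies, so their separate values are uncertain. The other 4 of the 10 steepest were Mir294, Mir302d, Mir302b and Mir292, described with their clusters.

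The steepest falls were in Mir206, Mir511, Mir223, Mir873, Mir876, Mir133a-1, Mir483, mmu-mir-6944 and Mir133a-2, apart from Mir182, whose slope of -2.68 rests on its values listed at 0. Mir182 was at 1669730 FPKM in MEF and 37508500 on day 5, and with the later values treated as missing its slope was 0.91. Its call in the fit as deposited was also lost without day 1, 2, 3, 6, 7 or 8 (adjusted p = 0.0682, 0.0685, 0.0637, 0.0705, 0.0998 and 0.136). Mir511, which lies in the macrophage mannose receptor gene, and Mir223, a myeloid miRNA, fell by 1.5 ± 0.16 and 1.49 ± 0.17 per day (adjusted p = 0.000506 and 0.000598). Mir223 was at 24400 FPKM in MEF and 21.6 on day 8, and Mir511 was at 12072 in MEF and listed at 0 from day 5. Mir483, in an Igf2 intron, fell by 1.14 ± 0.08 per day (adjusted p = 5.49e-05) and was 415-fold higher in MEF than on day 8. Mir873 and Mir876, neighbours on chromosome 4, fell by 1.30 ± 0.09 and 1.20 ± 0.16 per day. The slope of mmu-mir-6944 was -1.09 ± 0.11.

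All 7 tested members of the miR-290 cluster (chromosome 7, 3218626 to 3220841, GRCm38) rose, and 7 when adjusted over the list alone. Their median slope was 1.18 per day (camera adjusted p = 0.000103, adjusted p = 0.292 with an estimated correlation). Most of the climb came early: Mir292 was at 2780 FPKM in MEF, 62932 on day 1 and 1201450 on day 2, and reached 8860800 on day 8. Mir294 rose by 1.30 ± 0.20 per day (adjusted p = 0.00255) and was 3158-fold higher on day 8 than in MEF. Mir295 reached 31201600 FPKM on day 8. Without MEF the median slope was 0.78, within days 3 to 8 it was 0.35, and the slopes of Mir290 and Mir291a were 0.73 and 0.78 in place of 1.14 and 1.21. The slope of Mir291b was 0.94 ± 0.27 (adjusted p = 0.0345), with an adjusted p of 0.0995 and a slope of 0.47 without MEF, 0.0816 without day 1, 0.0553 without day 5 and 0.0667 without day 6.

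All 5 members of the miR-302 cluster (chromosome 3, 127545228 to 127545807) rose, and 5 when adjusted over the list alone. Their median slope was 1.11 per day (camera adjusted p = 0.000103, adjusted p = 0.248 with an estimated correlation). Mir302d was listed at 0 in MEF, at 4424 FPKM on day 2, 8128 on day 5 and 160446 on day 8. Mir302a rose by 1.11 ± 0.09 per day (adjusted p = 0.000142) and went from 75.5 FPKM in MEF, the worth of 1 read, to 65824 on day 8, and Mir302b rose by 1.22 ± 0.13 (adjusted p = 0.00056). The call of Mir367, at 0.87 ± 0.24 per day (adjusted p = 0.0276), was lost without MEF (adjusted p = 0.0788), day 1 (0.0776), day 6 (0.0543), day 7 (0.0712) or day 8 (0.127).

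Of 7 epithelial miRNAs, members of the miR-200 family with miR-203 and miR-205, 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. This list had a median slope of 0.57 (camera adjusted p = 0.0111, adjusted p = 0.248 with an estimated correlation), and without days 7 and 8 the adjusted p was 0.135 with a median of 0.81. Mir200b, Mir429 and Mir200a, neighbours on chromosome 4 known for restraining the mesenchymal regulators Zeb1 and Zeb2, rose by 0.70 ± 0.11, 0.69 ± 0.11 and 0.68 ± 0.09 per day. Mir200b was 20.8-fold higher on day 8 than in MEF. Mir200c rose by 0.57 ± 0.17 (adjusted p = 0.0392), a call lost without day 1 (0.0685), day 2 (0.0703), day 3 (0.052), day 6 (0.0726), day 7 (0.0992) or day 8 (0.194). The keratinocyte miRNA Mir203 fell, with a slope of -0.47 ± 0.11 (adjusted p = 0.018), a call lost without MEF (0.0694) or day 1 (0.0519). Mir205 had a slope of 0.53 (adjusted p = 0.0596) and was at 12933 FPKM on day 1 and 288255 on day 2. Without day 2 its slope was 0.60 (adjusted p = 0.0459).

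In the miR-183-96-182 cluster of sensory and pluripotent cells, Mir183 and Mir96 rose and Mir182 carried the values listed at 0. The counts were 2 rising and 1 falling among 3, and the same 2 and 1 when adjusted over the list alone. The list was not called (camera adjusted p = 0.347, adjusted p = 0.581 with an estimated correlation), with a median slope of 0.56 and a mean slope of -0.46. Mir96 rose by 0.75 ± 0.13 per day (adjusted p = 0.00412) and was 41.3-fold higher on day 8 than in MEF. Mir183 rose by 0.56 ± 0.15 (adjusted p = 0.0253), from 640015 FPKM in MEF to 36247800 on day 6. Its adjusted p was 0.11 without MEF, 0.0753 without day 1 and 0.0528 without day 6.

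Of 15 members of the proliferation-associated miR-17-92 cluster and its paralogs, 3 rose (Mir20b, Mir363 and Mir106a), and 3 when adjusted over the list alone. The median slope was 0.50 (camera adjusted p = 0.0344, adjusted p = 0.404 with an estimated correlation), and 0.23 without the 6 members listed at 0 on day 2. Mir20b and Mir363, in the X-linked paralog, rose by 0.63 ± 0.12 and 0.52 ± 0.10 per day. Mir106a rose by 0.59 ± 0.18 (adjusted p = 0.0455) and kept its call in 1 of the 9 fits that left out a library, the one without day 2, with a slope of 0.26 without MEF. The adjusted p of the list was 0.0694 without MEF (median slope 0.43), 0.0665 without day 2 (0.09) and 0.0604 without day 8 (0.50), and within days 3 to 8 the median slope was -0.19. Mir25, the most abundant member with a value in every library, had a slope of 0.05.

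Most tested members of the fibroblast, let-7 and miR-99-100-125 lists fell over the course. Day 3 was the first stage on human fibroblast feeders, at which Mir654 went from 147 to 297835 FPKM. On day 3, 6 of 8 fibroblast, 3 of 11 let-7 and 5 of 6 miR-99-100-125 members were higher than on day 2. So were 65 of 71 Sfmbt2, 7 of 7 miR-290, 6 of 8 neural and 26 of 43 Dlk1-Dio3 members. In other lists fewer were, such as 1 of 6 muscle, 24 of 75 C/D box and 10 of 32 H/ACA box members. A rise at this step was therefore not particular to the fibroblast and miR-99-100-125 lists. The course ended in days 7 and 8, with their low share of reads in the table. In the fibroblast and mesenchymal list 5 of 8 fell, and 5 when adjusted over the list alone, with a median slope of -0.32 (camera adjusted p = 0.00105, adjusted p = 0.248 with an estimated correlation). Within days 3 to 8 alone the median slope was -0.31 (adjusted p = 0.00124), and after quantile normalization -0.20 (adjusted p = 0.0490). Mir21 fell by 0.37 ± 0.06 per day (adjusted p = 0.00396), from 15382600 FPKM in MEF to 2673370 on day 8, and Mir214, from the Dnm3 antisense transcript, fell by 0.57 ± 0.11 (adjusted p = 0.00535). Mir199a-1, Mir199a-2 and Mir199b, near-identical copies whose split is uncertain, had slopes of -0.34, -0.34 and -0.29. The call of Mir199a-1 was lost without MEF (adjusted p = 0.0533), and that of Mir199b without MEF (0.0788), day 1 (0.0635), day 7 (0.0643) or day 8 (0.0574). Mir143 was listed at 0 in MEF and went from 40549900 FPKM on day 1 to 7360140 on day 8. Its slope was 1.15 (adjusted p = 0.303) as deposited and -0.32 (adjusted p = 0.0189) without MEF.

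The let-7 family, which is associated with differentiation, had 6 falling members of 11, and 7 when adjusted over the list alone. The median slope was -0.27 (camera adjusted p = 0.000302, adjusted p = 0.292 with an estimated correlation), and -0.17 without days 7 and 8 (adjusted p = 0.0033). Mirlet7i, the most abundant member, fell by 0.43 ± 0.07 per day (adjusted p = 0.00274), from 8414990 FPKM in MEF to 869298 on day 8. Mirlet7d and mmu-let-7j fell by 0.42 ± 0.07 and 0.50 ± 0.08. The other falling members were less secure. Mirlet7f-2 (-0.25, adjusted p = 0.0455) kept its call without MEF or day 4 and lost it in the other fits that left out a library (adjusted p from 0.0512 without day 3 to 0.138 without day 8). Mirlet7c-1 and Mirlet7c-2 (both -0.27) lost theirs without day 1 (0.0537 and 0.0534), day 7 (both 0.0671) or day 8 (0.0818 and 0.0839). The copies of let-7a, let-7c and let-7f share mature sequences. Mirlet7b had a slope of -0.00 (adjusted p = 0.987), with 162000 FPKM on day 2 and 339796 on day 3.

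In the miR-99-100-125 clusters, neighbours of let-7 genes, 5 of 6 fell, and 5 when adjusted over the list alone. Together they had a median slope of -0.38 (camera adjusted p = 0.000416, adjusted p = 0.248 with an estimated correlation). Mir99b fell by 0.44 ± 0.08 per day (adjusted p = 0.00463) and Mir125b-1 by 0.49 ± 0.07 (adjusted p = 0.00178). Mir100 had a slope of 0.01 (adjusted p = 0.987), and was at 170633 FPKM on day 2 and 1224150 on day 3. The fall of Mir99a (-0.24 ± 0.07, adjusted p = 0.0345) was lost without MEF (0.0868), day 5 (0.0539), day 6 (0.0506), day 7 (0.085) or day 8 (0.103).

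All 6 muscle miRNAs fell, and 6 when adjusted over the list alone, with a median slope of -1.04 (camera adjusted p = 3.47e-06, adjusted p = 0.248 with an estimated correlation). Mir133a-1 fell by 1.16 ± 0.13 per day (adjusted p = 0.000598), from 60284 FPKM in MEF to 65.9 on day 8. Mir1a-1 fell by 0.99 ± 0.13 (adjusted p = 0.00111). Mir206, restricted to skeletal muscle in the adult, fell by 1.5 ± 0.18 (adjusted p = 0.000721), from 31309 FPKM in MEF to 2577 on day 2. Mir133a-1 and Mir133a-2 share their mature sequence. The call of Mir133b (-0.66 ± 0.19, adjusted p = 0.0317) was lost without MEF (0.138, slope -0.43), day 1 (0.0918), day 5 (0.0514), day 6 (0.0598) or day 7 (0.0547).

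Of 6 Hox cluster miRNAs, Mir10b and Mir615 fell, 2 when adjusted over the list alone. Mir10b, next to Hoxd4, was at 38849200 FPKM in MEF and fell by 0.62 ± 0.07 per day (adjusted p = 0.000778) to 1745500 on day 8. Mir615, within Hoxc5, fell by 0.66 ± 0.09 (adjusted p = 0.00125). The list had a median slope of -0.10 (camera adjusted p = 0.0319, adjusted p = 0.344 with an estimated correlation). Without MEF, where Mir10a was listed at 0, the median was -0.41, without day 7 it was -0.05, and the adjusted p was 0.0604 without day 8 and 0.113 without days 7 and 8, where the median was 0.01.

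In the X-linked miR-322 cluster (53047997 to 53054349), which restrains the cell cycle, 6 of 7 fell, and 7 when adjusted over the list alone, with 4 of the 6 called in every fit that left out a library. The cluster's median slope was -0.43 (camera adjusted p = 5.26e-05, adjusted p = 0.248 with an estimated correlation). Mir351 fell by 0.87 ± 0.10 per day (adjusted p = 0.000721), from 5352610 FPKM in MEF to 71292 on day 8, and Mir322 by 0.49 ± 0.08 (adjusted p = 0.00415). Mir34c and Mir34b, targets of p53, fell by 0.49 ± 0.06 and 0.52 ± 0.07, 2 of 3 in the miR-34 family and 2 when adjusted over the list alone. The family had a median slope of -0.49 (camera adjusted p = 0.0349, adjusted p = 0.292 with an estimated correlation), with 0.0763 without MEF (median -0.49) and 0.0604 without day 8 (median -0.50). Mir34a had a slope of 0.10. The miR-29 family, which targets collagen genes, was not called (camera adjusted p = 0.0802, adjusted p = 0.344 with an estimated correlation). In it, 2 of 4 fell, and 2 when adjusted over the list alone. These were Mir29b-1 and Mir29b-2, near-identical copies (adjusted p = 0.0439 and 0.0384). Mir29b-1 lost its call in each fit that left out a library except those without MEF or day 4 (adjusted p up to 0.105 without day 7), and Mir29b-2 in each but the one without day 4 (up to 0.0911 without day 1).

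Among markers of other cell types, the blood cell miRNAs fell as a list, with 2 falling of 6, and 2 when adjusted over the list alone. The median slope was -0.37 (camera adjusted p = 0.0344, adjusted p = 0.248 with an estimated correlation), and 0.212 was the adjusted p without MEF, with a median of -0.20. Without day 8 the median was -0.56. The falling members were Mir223 and Mir486, an erythroid and muscle miRNA that fell by 0.47 ± 0.09 per day (adjusted p = 0.00575). Mir142 had a slope of -0.44 (adjusted p = 0.0966), and -0.68 without day 8 (adjusted p = 0.0169). It was at 232146 FPKM in MEF, 5752 on day 5, 46201 on day 8, 563551 in iPSC and 187969 in ESC. Mir150, a lymphocyte miRNA, had a slope of 0.33 (adjusted p = 0.218) and was at 2493 FPKM in MEF and 103473 on day 6. Of 8 neural miRNAs 0 changed linearly by limma, also when adjusted over the list alone, with a median slope of 0.01 (camera adjusted p = 0.898, adjusted p = 0.955 with an estimated correlation). Without days 7 and 8 the list was called, with a median of 0.40 (adjusted p = 0.0300). The near-identical Mir9-2 and Mir9-3 went from 79039 and 70704 FPKM in MEF to 425230 and 386640 on day 6 and 44173 and 40703 on day 8. The endothelial Mir126, too few for a list test, had a slope of 0.05 (adjusted p = 0.738).

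**Figure D2:**
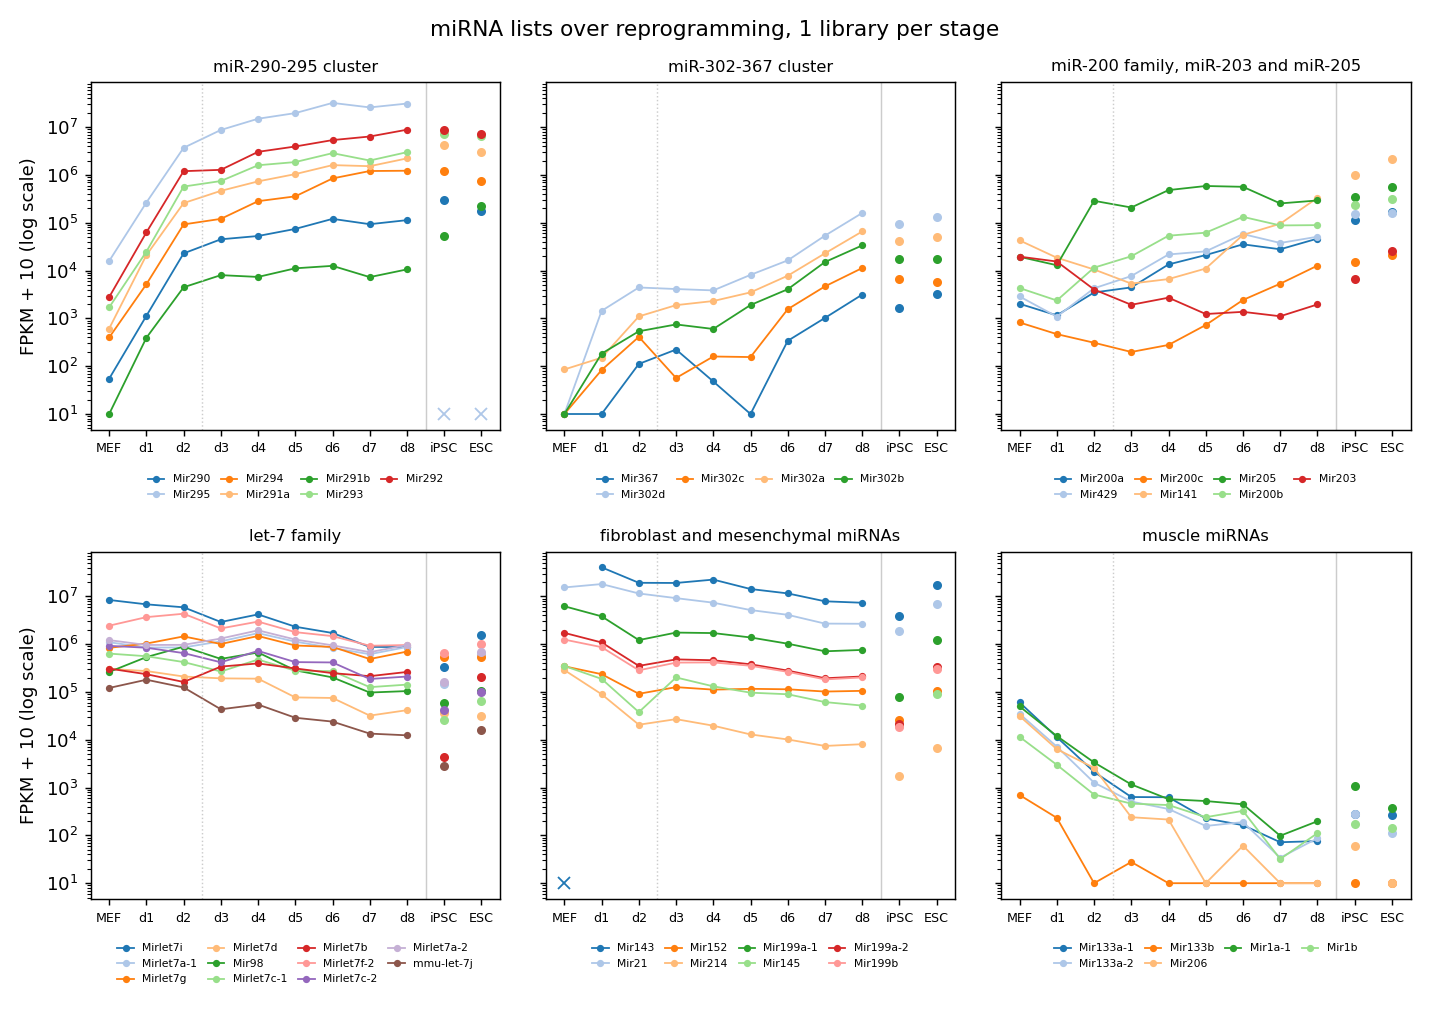
FPKM + 10 on a log axis for the members of 6 lists over MEF, days 1 to 8 (d1 to d8), iPSC and ESC, 1 point per library, with lines joining the course, crosses for abundant transcripts listed at 0, a dotted line before day 3, the first stage on human feeder cells, and a solid line between the course and the lines. The miR-290 members climbed from MEF to day 2 (Mir292 from 2780 to 1201450 FPKM), the miR-302 members later (Mir302d 8128 on day 5 and 160446 on day 8), and the muscle miRNAs declined (Mir133a-1 from 60284 to 65.9).

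Of 43 miRNAs of the Dlk1-Dio3 region (chromosome 12, 109563692 to 109743795), 10 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone, while 3 of the 10 kept the call in every fit that left out a library. The median slope was -0.15 (camera adjusted p = 0.000103, adjusted p = 0.404 with an estimated correlation). The median was -0.08 without day 8, and 0.03 (adjusted p = 0.113) without days 7 and 8, whose share of reads in the table was lowest. The rising member was Mir654. Mir541 fell by 0.39 ± 0.10 per day (adjusted p = 0.0251), a call lost without MEF (0.0605), day 7 (0.0671) or day 8 (0.125). Mir127 was listed at 0 in MEF and on day 4 and went from 20991000 FPKM on day 1 to 4005250 on day 8.

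The next list was named for the large miRNA cluster in an intron of Sfmbt2. Of its 71 tested members, 57 lay on chromosome 2 between 10466663 and 10518279, 2 lay on other chromosomes and 12 had no location in the annotation. In this list 44 of 71 rose and 0 fell by limma, and 59 rose when adjusted over the list alone, but 5 of the 44 kept the call in every fit that left out a library. The median slope was 0.44 (camera adjusted p = 8.67e-17, adjusted p = 0.323 with an estimated correlation). Mir467e rose by 0.72 ± 0.11 per day (adjusted p = 0.00195), from 4250 FPKM in MEF to 136364 on day 8, and Mir669o rose by 0.55 ± 0.12 (adjusted p = 0.0114). Mir467d rose by 0.37 ± 0.11 (adjusted p = 0.0323), a call lost without MEF (0.0968), day 1 (0.0873), day 2 (0.0502), day 5 (0.0522) or day 6 (0.0578). Within days 3 to 8 the median slope was 0.08 (adjusted p = 0.0604), and without days 7 and 8 it was 0.81. The members are near-identical, so the split between them is uncertain.

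A part of the small nucleolar RNAs, which guide rRNA modification, rose. Of 75 C/D box snoRNAs 9 rose and 0 fell by limma, and 7 rose when adjusted over the list alone, with a median slope of 0.12 (camera adjusted p = 0.00949, adjusted p = 0.557 with an estimated correlation). The adjusted p was 0.124 without MEF (median -0.02), 0.181 without day 8 (median 0.09) and 0.827 without days 7 and 8 (median 0.13). Without day 1 the median was 0.20. Of 32 H/ACA box snoRNAs 8 rose, and 8 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0173, adjusted p = 0.457 with an estimated correlation). Without MEF the adjusted p was 0.0763 (median 0.10), without day 8 0.159 (median 0.09) and without days 7 and 8 0.498 (median 0.14). Of the 9 C/D and 8 H/ACA calls, 4 and 4 held in every fit that left out a library. Snord73a rose by 0.80 ± 0.11 per day (adjusted p = 0.00125), from 6135 FPKM in MEF to 532237 on day 8, and Snora33 by 0.47 ± 0.08 (adjusted p = 0.00412). The abundant C/D member Snord69 was at 44885 FPKM in MEF, 396553 on day 1 and 283649 on day 8, with a slope of 0.14 (adjusted p = 0.59).

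Of 9 Cajal body RNAs, Scarna3a and Scarna3b fell, and 2 fell and 1 rose when adjusted over the list alone. The list was not called (median slope -0.03, camera adjusted p = 0.529, adjusted p = 0.772 with an estimated correlation). Scarna3a fell by 0.37 ± 0.09 per day (adjusted p = 0.0181). Scarna3b (-0.28 ± 0.08, adjusted p = 0.0391) lost its call without MEF (0.0805), day 1 (0.0889), day 2 (0.0611), day 5 (0.0602), day 6 (0.0689) or day 7 (0.0979). Of 4 Prader-Willi locus snoRNAs 1 rose, Snord107, and 2 when adjusted over the list alone. The list was not called (median 0.30, camera adjusted p = 0.0547, adjusted p = 0.248 with an estimated correlation), but was past the threshold without day 1 (0.0297), day 4 (0.0429) or day 6 (0.0374). Snord107 rose by 0.55 ± 0.16 (adjusted p = 0.0358), from 72.6 FPKM in MEF to 8837 on day 8. It kept the call without day 1 or 2 and lost it in the other 7 fits, with a slope of 0.26 without MEF and an adjusted p up to 0.0883 without day 8. Of the 21 lists tested, 16 were called with the preset correlation, 7 rising and 9 falling, and 0 with a correlation estimated from the data, where camera gave 3 lists an unadjusted p under 0.05. By fry, which does not compare a list with other transcripts, 14 were called, 12 of them among the 16.

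A second test asked for any change, including a rise and fall within the course. The transcripts that peaked in mid-course included Mir4660, Mir3078, Mir297-1 and mmu-mir-7211, and among those with a low was Mir3475. In all 463 transcripts changed by limma's F-test of day and day squared, of which 162 had no linear trend, and without days 7 and 8 the count was 218. Of the 162, 136 had the fitted peak within the course and 26 the fitted low, but the split was 76 and 71 after median ratios and 82 and 70 after quantile normalization. Mir3078 was at 76.9 FPKM in MEF, 14660 on day 3 and 348 on day 8 (adjusted p = 0.000629). Mir4660, at chromosome 2, 10472540 to 10472623, within the Sfmbt2 cluster, was listed at 0 in MEF, at 7286 on day 6 and 1291 on day 8 (adjusted p = 0.00147). Mir297-1 and mmu-mir-7211 had their highest values on day 5, at 1491 and 1523 (adjusted p = 0.000603 and 0.000426), and with day 8 left out their linear slopes of 0.81 and 0.79 passed the threshold (adjusted p = 0.045 and 0.038). Mir3475 was at 992 on day 1 and listed at 0 on days 3 to 6 (adjusted p = 0.0317). Without day 7 it had a slope of -0.93 (adjusted p = 0.0293). The neural Mir124a-3, Mir124a-1 and Mir124a-2, near-identical copies, also changed (adjusted p = 0.00708, 0.00466 and 0.00244), with 1248 FPKM of Mir124a-3 in MEF, 11001 on day 4 and 1231 on day 8.

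The end points of the course were compared next, with 1 library each and no replicate check. Both pluripotent lines stood above MEF in the miR-290 and miR-302 clusters and below it in muscle and fibroblast miRNAs. Relative to MEF, the mean of the lines was higher by a median of 12.00 (log2) over 6 miR-290 members, percentile 100 among 10000 random lists matched on expression. The random lists held transcripts drawn singly, whereas cluster members move together (estimated correlation over the course 0.99 for miR-290 and 0.88 for Sfmbt2). Percentiles here and between the lines can therefore overstate how unusual a list is. The median was 9.29 for miR-302, 5.12 for the miR-200 list (percentile 99.8), 4.59 for the 9 miR-17-92 paralogs not listed at 0 (percentile 99.9) and 3.60 for the Sfmbt2 list, which was 2.22 after median ratios and 1.76 after quantile normalization. It was -6.95 for muscle, -4.04 for fibroblast, -3.80 for miR-99-100-125 and -3.16 for let-7 miRNAs, all at or below percentile 0.035. The lines differed on these lists: the medians in iPSC and ESC were -6.06 and -2.02 for fibroblast, -5.09 and -2.40 for miR-99-100-125, -3.07 and -1.35 for let-7 and -6.55 and -7.45 for muscle miRNAs. At least 4-fold lower in both lines were 6 of 6 muscle, 4 of 7 fibroblast, 2 of 6 miR-99-100-125 and 5 of 11 let-7 miRNAs. These figures stand against a shift of all transcripts, whose median difference from MEF was 1.36 in iPSC and 0.98 in ESC as deposited and 0.08 and 0.00 after rescaling by median ratios.

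Single transcripts showed the range. Mir291a was at 602 FPKM in MEF, 4158000 in iPSC and 3069750 in ESC, and Mir293 at 1692, 7237250 and 6430410. Mir302d and Mir291b were listed at 0 in MEF and at 132602 and 227511 in ESC. The other 6 of the 10 largest rises, Mir127, Mir143, Mir136, Mir434, Mir10a and Mir431, were the abundant transcripts listed at 0 in MEF. Among the 10 largest declines Mir182 and Mir295 were likewise listed at 0 in both lines. The others were Mir223, Mir511, Mir3093 and Mir133b, listed at 0 in both lines, Mir206, Mir133a-1, Mir133a-2 and Mir1b. Mir206 was at 50.4 in iPSC and listed at 0 in ESC. In total 421 transcripts were at least 4-fold higher in both lines and 110 lower, and 410 and 108 without the abundant transcripts with values listed at 0. After rescaling by median ratios these were 240 and 223, and after quantile normalization 215 and 222. Of the 421, 143 were listed at 0 in MEF.

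Apart from Mir183 and Mir96, given last, the remaining lists had smaller medians as deposited than the lists above of the same direction. They were 3.42 for Prader-Willi snoRNAs (percentile 98.1), 2.72 for C/D box snoRNAs (percentile 99.9) and 1.95 for H/ACA box snoRNAs (percentile 90.8). After rescaling by median ratios these were 2.54, 1.42 and 0.77, and after quantile normalization 2.22, 1.18 and 0.30. Medians were -2.11 for Hox (percentile 1.24), -1.71 for blood cell (percentile 1.13), -1.40 for miR-34 (percentile 9.6), -1.36 for Dlk1-Dio3 (percentile 0), -1.33 for miR-29 (percentile 2.87) and -0.07 for miR-322 miRNAs (percentile 13.0). In the same order they were -3.52, -3.08, -2.81, -2.77, -2.74 and -1.49 after median ratios and -3.35, -3.50, -2.16, -2.36, -2.60 and -1.18 after quantile normalization. Between iPSC and ESC the medians against MEF differed for Hox (-3.19 and -1.04), blood cell (-2.66 and -0.79), miR-34 (-0.29 and -2.51), miR-29 (-1.49 and -0.82), H/ACA (2.26 and 1.28) and miR-322 (0.73 and -0.88 as deposited, -0.74 and -2.23 after median ratios, and -0.68 and -1.99 after quantile normalization). The neural median was 1.05 as deposited and -0.33 after either rescaling, and that of Cajal body RNAs 1.11 as deposited, 0.07 after median ratios and -0.55 after quantile normalization. Mir150 was at 2493 FPKM in MEF, 214088 in iPSC and 102402 in ESC, and Mir126 at 44995, 204018 and 231538. Mir183 and Mir96 were 59.9-fold and 180-fold higher in ESC than in MEF as deposited. Their median difference (log2) was 6.69 as deposited, 5.34 after median ratios and 5.7 after quantile normalization.

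The iPSC line was then compared with the ESC line, its positive control, again with 1 library each and no replicate check. The fibroblast, let-7 and miR-99-100-125 medians were lower in iPSC and those of the miR-34 and miR-322 miRNAs were higher. The miR-290 median was 0.37 higher in iPSC (percentile 88.5), although Mir291b was at 54055 FPKM in iPSC and 227511 in ESC, and the miR-302 median -0.33 (percentile 13.2). Fibroblast miRNAs stood at -2.13 (percentile 0.05), miR-99-100-125 at -2.36 (percentile 0.15), let-7 at -1.31 (percentile 0.13) and the Sfmbt2 list at -0.98 (percentile 0). Beside these groups, Mir654 was at 67.5 FPKM in iPSC and 164921 in ESC, and both lines were labelled as grown on human feeders. Mir100 was at 6216 and 602545 FPKM, Mirlet7b at 4367 and 210276, and Mir199a-1 at 79285 and 1197780. Mir467e of the Sfmbt2 list was at 14552 in iPSC and 220186 in ESC.

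Higher in iPSC were miR-34 at 2.22 (percentile 100) and miR-322 at 1.61 (percentile 100). The Hox miRNAs had no clear direction. Their median difference was 0.95 (percentile 98.1), but their median against MEF was lower in iPSC (-3.19) than in ESC (-1.04). Of 5 Hox members, 1 was at least 4-fold lower in iPSC and 0 at least 4-fold higher. Mir351 was at 1841990 FPKM in iPSC and 188758 in ESC, and Mir34c at 604658 and 129548. The other medians were 0.79 for H/ACA box snoRNAs (percentile 97.0), 0.76 for muscle (percentile 75.6), 0.42 for miR-17-92 (percentile 92.5), 0.40 for Cajal body RNAs (percentile 68.1), 0.24 for neural miRNAs (percentile 57.5), 0.22 for C/D box snoRNAs (percentile 82.6) and 0.11 for Dlk1-Dio3 (percentile 53.5), which was -0.01 after rescaling by median ratios and 0.02 after quantile normalization. After these rescalings the H/ACA median was 0.65 and 0.36, muscle 0.64 and 0.35, miR-17-92 0.30 and 0.14, Cajal body 0.28 and 0.18, neural 0.12 and 0.22, and C/D 0.10 and 0.07. Medians below 0 were -0.12 for Prader-Willi snoRNAs (percentile 30.4; -0.23 and -0.32 after rescaling), -0.31 for miR-29 (percentile 25.6), -0.49 for blood cell miRNAs (percentile 4.28) and -0.62 for the miR-200 list (percentile 4.7).

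Between the lines, 154 transcripts were at least 4-fold higher in iPSC and 101 lower, but 114 and 110 after quantile normalization. The largest differences upward were Mir344d-1 (1534 FPKM in iPSC, listed at 0 in ESC), Snord21, Mir3475, the X-linked Mir742 (6951 and 116) and Gm24421 (518 and listed at 0). Downward they were Mir654, Gm24899 (50.4 and 14177), mmu-mir-7688 and Mir1948, both listed at 0 in iPSC and at 2336 and 2312 in ESC, and Mir100.

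**Figure D3:**
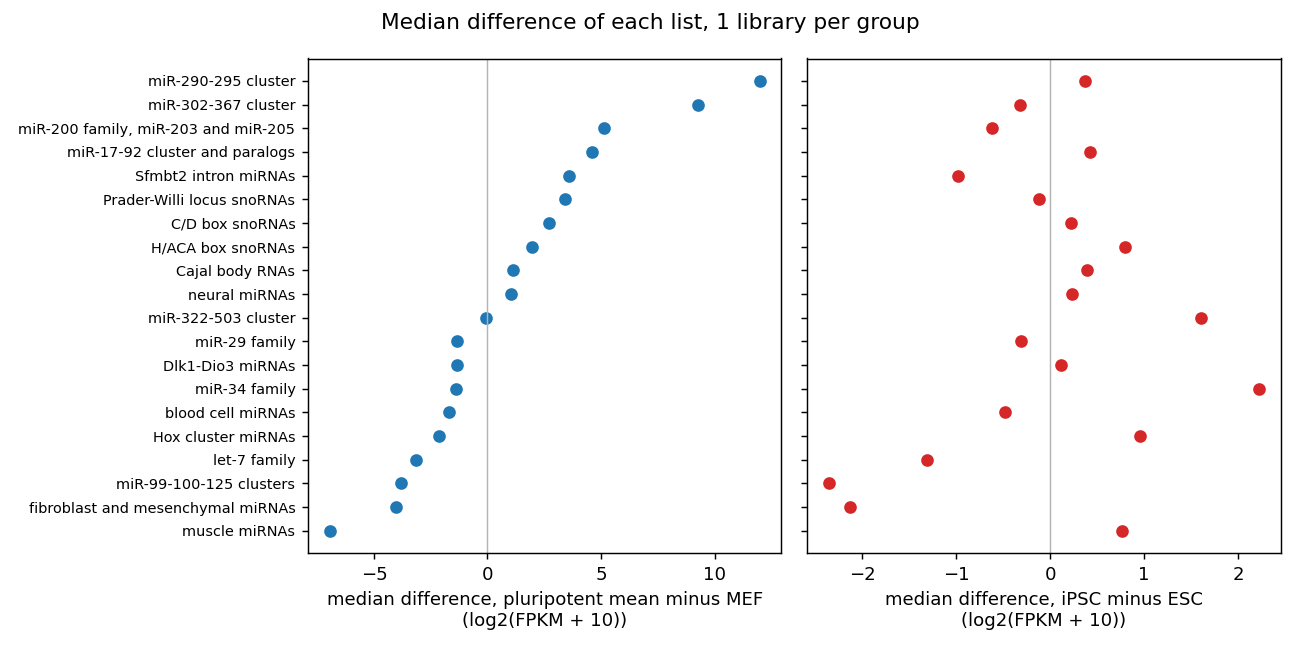
Median difference in log2(FPKM + 10) of the members of each list, for the mean of iPSC and ESC minus MEF (left) and iPSC minus ESC (right), 1 point per list and 1 library per group, leaving out abundant transcripts listed at 0. The miR-290 median was 12.00 above MEF, the muscle median was -6.95, and between the lines the miR-99-100-125 and fibroblast medians were -2.36 and -2.13, while rescaling turned the left medians of neural miRNAs (-0.33) and Cajal body RNAs (-0.55, quantile normalization) and the right one of Dlk1-Dio3 (-0.01, median ratios) negative.

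The last comparison asked when the course approached the pluripotent lines, again with 1 library per stage and no replicate check. Day 1 stood part of the way from MEF to the lines, and day 8 stood short of them. The 1 MEF library enters both the position and the axis, so its own scatter moves every other library towards the lines. The scatter of iPSC and ESC, with 1 library each, lengthens the axis and lowers the position of every day. A shortfall of day 8 can therefore come in part from the measure itself. On the axis from MEF (0%) to the mean of the lines (100%), day 1 was at 48.6%, day 2 at 57.6%, day 3 at 62.1%, day 4 at 56.0%, day 5 at 72.7%, day 6 at 80.9%, day 7 at 74.6% and day 8 at 81.9%. The 95% interval of day 8 over 500 bootstrap draws of transcripts was 77.5% to 85.3%, which leaves out the spread between cultures. Without the 15 abundant transcripts with values listed at 0, 5 of them at 0 in both MEF and day 4, day 1 was at 42.1%, day 3 at 59.0% and day 4 at 61.2%. Day 7 lay below day 6 as deposited but above it after median ratios (88.4% against 82.8%) and quantile normalization (87.2% against 81.6%). Spearman's rho with ESC across transcripts, which are not independent replicates, was 0.769 for MEF, 0.849 for day 1, 0.900 for day 6, 0.890 for day 8 and 0.924 for iPSC.

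Between consecutive stages, 734 transcripts changed at least 2-fold from MEF to day 1, 540 of them higher and 194 lower, and 526 and 194 without the abundant transcripts with values listed at 0. After median ratios, which put MEF at 0.546 and day 7 at 0.599 of the typical library, 375 were higher and 370 lower, and after quantile normalization 365 and 343. Among the higher were Mir292 at 22.6-fold and Snord69 at 8.83-fold higher, and Mir351 was at 2202510 FPKM on day 1 against 5352610 in MEF. From day 6 to day 7, the library with the lowest share of reads in the table, 749 changed as deposited, 93 higher and 656 lower, but 240 were higher and 266 lower after median ratios, and after quantile normalization the balance turned to 276 higher and 257 lower. From day 7 to day 8, 399 were higher and 97 lower, and 269 and 179 after median ratios. The steps from day 1 to day 6 had 632, 542, 562, 506 and 469.

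**Figure D4:**
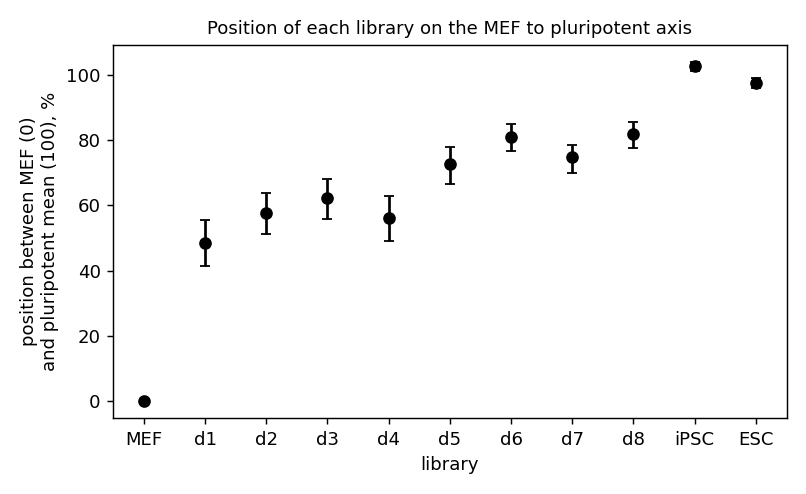
Position of each of the 11 libraries, in percent, on the axis from MEF (0) to the mean of iPSC and ESC (100), with bars for the 95% interval over 500 bootstrap draws of transcripts, 1 library per stage. Day 1 stood at 48.6%, day 8 at 81.9% and day 7 at 74.6%, below day 6 as deposited but above it after median ratios (88.4%) or quantile normalization (87.2%), and iPSC and ESC lie near 100 because their mean sets the axis.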

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

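Treating zeros of abundant transcripts as missing, leaving out days 7 and 8 and scaling to recovered miRNA reads were chosen after the results were seen. The cause was not tested for any change below, apart from settings that test fewer or more transcripts or use fewer libraries. No paired analysis was possible because each stage had 1 library. Of the alternative values of counts, 129 stayed within 1.5 times and 51 did not. Of 21 alternative positions of days 1, 4 and 8 on the axis to the lines, 19 stayed within the bootstrap interval, and of 3305 alternatives for named transcripts 2954 kept direction and side of the threshold, 256 lost the call, 84 gained one and 11 reversed. Of 77 named transcripts called, 53 kept the call without any 1 library. The 177 rising transcripts became 72 without a filter, 66 within days 3 to 8 and 75 by the exact Spearman test, and 93 (without MEF) to 175 (without day 4) with 1 library left out. Among miRNAs tested alone 111 rose, against 105 miRNAs among the 177. The 150 falling became 95 without a filter, 80 within days 3 to 8 and 69 without days 7 and 8, and 97 (without day 7) to 170 (without MEF) with 1 library left out. Rising transcripts made 54.1% of the calls, 35.4% without MEF and 72.4% without days 7 and 8. Among miRNAs tested alone they made 41.3%, where all 105 rising and 146 falling miRNA calls of the main fit were kept. With reads scaled to recovered miRNA reads, also over miRNAs alone, they made 61.1%. The 463 with any change became 305 without a filter and 218 without days 7 and 8. The number of lists called, 16 as reported, was 10 without days 7 and 8 (9 of the 16, with the neural list gained), 0 with an estimated correlation (lowest adjusted p = 0.248), and 11 (without MEF or day 8) to 17 (without day 1, 4 or 6, all 16 with the Prader-Willi list gained) with 1 library left out. The blood cell and miR-34 lists were not called after median ratios (both 0.0749), quantile normalization (0.0847 and 0.101), at a mean of at least 100 (both 0.0811), against a miRNA background (0.142 and 0.121) or within days 3 to 8 (0.771 and 0.0906). The Hox and H/ACA lists were not called after quantile normalization (both 0.0701) or at a mean of at least 100 (0.0811 and 0.0920), nor Hox against a miRNA background (0.121). By fry the C/D, Dlk1-Dio3, miR-17-92 and H/ACA lists were not called (0.125, 0.0510, 0.0730 and 0.05004). Without days 7 and 8 the miR-17-92 and miR-34 lists were not called (both 0.0838, medians 0.69 and -0.48). The Prader-Willi list was called at pseudocount 1 (0.0431), without a filter (0.00236), within days 3 to 8 (0.0182) and by fry (0.00455), and miR-29 without a filter (0.00226) and by fry (0.00958). Within days 3 to 8 the called medians of the muscle, Hox, Dlk1-Dio3 and miR-322 lists were -0.62, -0.50, -0.36 and -0.21, and without a filter those of the miR-290, C/D and Dlk1-Dio3 lists were 0.47, 0.03 and -0.06. The H/ACA median was 0.08 at pseudocount 100. Within days 3 to 8 the miR-17-92 median turned to -0.19 and the slopes of Mir654, Gm24899, Mir3078, Gm24421 and Mir10a to -0.27, -0.15, -1.12, -1.23 and -0.98. With zeros missing, the slopes of Mir10a, Mir127, Mir143 and Mir182 were -0.78, -0.34, -0.32 and 0.91, which that setting's construction explains. With 1 library left out, Mir10a ranged from -0.78 (without MEF) to 1.07 (without day 8) and Mir143 from -0.32 (without MEF) to 1.63 (without day 1). For the lines against MEF, the 421 higher became 240 after median ratios and 215 after quantile normalization. The 110 lower became 223 and 222 under those, 70 at pseudocount 100, 71 at a mean of at least 100 and 194 at 2-fold. Between the lines, the 154 higher in iPSC became 50 at pseudocount 100, 92 at a mean of at least 100 and 330 at 2-fold, and the 101 lower 41, 49 and 230. Day 8 stood at 89.9% after median ratios and 88.9% after quantile normalization, and the 734 transcripts from MEF to day 1 became 489 at pseudocount 100 and 399 at 4-fold. Depth limits transcripts near 1 read, worth 26.4 to 49.8 FPKM at 80 nt, above the filter of 10.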

Other observations

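The tests of the order of the libraries, of the values listed at 0, of the transcripts that appeared on day 3 and of the falling transcripts were chosen after the results were seen, and so were the X-linked cluster, Mir675 and Mir483 as subjects.

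A cluster of 18 miRNA genes on the X chromosome (66776757 to 66839125, GRCm38), known from the testis, rose over the course and was far higher in the iPSC than in the ESC line. All 18 rose by limma, with slopes from 0.52 to 1.33 and a median of 1.08 per day. Without 1 library, 16 kept the call in every fit. Mir742 lost it without day 8 (adjusted p = 0.103), and Mir743 without MEF (0.0757), day 2 (0.0602), day 6 (0.0618), day 7 (0.0756) or day 8 (0.104). Mir470 was at 419 FPKM in MEF, 170927 on day 8, 4871230 in iPSC and 251903 in ESC, and Mir871 was at 944, 133407, 3667170 and 237606. All 18 were at least 4-fold higher in iPSC than in ESC, by a median of 4.34 (log2, from 3.59 to 5.79; 4.22 after median ratios and 4.28 after quantile normalization). The cluster took 3.18% of the recovered reads in iPSC, 0.188% in ESC and 0.214% on day 8. The Mir465 copies are near-identical, so the split between them is uncertain, and with 1 library per line there is no replicate check.

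The miRNAs of the imprinted H19 and Igf2 genes on chromosome 7 fell together. Mir675, made from H19, fell by 1.05 ± 0.09 per day (SE; limma adjusted p = 0.000127), from 11519 FPKM in MEF to 20.3 on day 8, which is near the worth of 1 read. Mir483 fell by 1.14 ± 0.08 (adjusted p = 5.49e-05), and it was at 3982 FPKM in iPSC and 715 in ESC. Both kept their call in all 9 fits that left out a library.

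Among 100 orders of the 9 libraries, the real one included, 1 gave as many linear calls as the real order, which was the real order with 327. The highest other order gave 98, and it was close to the real one, with a rank correlation of 0.88. The next gave 11. For any change the real order gave 463 calls, again 1 of 100, and the highest other 7. An unordered scatter of these libraries is therefore excluded as the source of either count, which says nothing about the spread between cultures.

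Abundant transcripts were listed at 0 in single libraries, 25 values in 15 transcripts. A locus silent in those libraries is argued against for the 7 transcripts with neighbours of the same cluster, whose values there stood 0.97 (log2) above the nearest library, as the median of the medians per transcript and library over 47 values (from -1.18 to 4.42), with neighbours shared by Mir127, Mir431, Mir433 and Mir434. For the other 8 no neighbour was compared. Of these, Mir136 lies beside Mir434 and was listed at 0 in the same libraries, MEF and day 4. The neighbours of Mir434 stood 0.36 to 1.71 (log2) higher there, which argues against a silent locus for Mir136 too. For the rest, silence cannot be told apart from a failed value. Exact zeros made 4.1% of the values (7 of 170) where the other libraries held a median of 100000 reads or more and 0.54% (9 of 1680) at 1000 to 10000 reads, from 5 and 7 transcripts. A failed estimate at heavily read loci was not tested, since the zeros were noticed in such transcripts.

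Some transcripts appeared on day 3, the first stage labelled as on human feeder cells. The 23 transcripts at least 8-fold above MEF, day 1 and day 2 had a median of 4.01 reads on day 3. Their median in ESC stood 0 above those stages. Over the 23 as a set, small RNA of human feeder cells in days 3 to 8 and ESC cannot be told apart from scatter at that depth. A minimum of 100 reads, set after that 0 was seen, left Mir654, Gm24899 and Gm25802, whose median was 10.21 on day 3, 9.36 in ESC and -0.30 in iPSC, where they were at 67.5, 50.4 and 43.3 FPKM. On days 4 to 8 their median lay between 8.43 (day 4) and 9.69 (day 5), which argues against scatter at low depth for these 3. Feeder RNA in days 3 to 8 and ESC stays open for them, because feeders, medium and later days cannot be separated. The -0.3 in iPSC argues, for these 3, against feeder RNA in the iPSC library at the level of ESC and equally (-0.3) against a program shared by pluripotent cells. The fibroblast list stood lower in iPSC than in ESC (percentile 0.05, 7 members, all with values in MEF). Mir21 was at 1929470 and 7054880 FPKM and Mir199a-1 at 79285 and 1197780. Fibroblast small RNA in the ESC and not in the iPSC library could give this, while a difference between the lines themselves stays open and untested. Other falling lists went both ways. The let-7, miR-99-100-125 and blood cell medians were lower in iPSC (-1.31, -2.36 and -0.49). Those of miR-34, miR-322, muscle and Dlk1-Dio3 miRNAs were higher as deposited (2.22, 1.61, 0.76 and 0.11). The Hox list had no clear direction, with a median difference of 0.95 but medians against MEF of -3.19 in iPSC and -1.04 in ESC.

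Days 7 and 8 had the lowest share of reads in the table, 22.6% and 27.5%, and 150 transcripts fell over the course. Of these, 66 were also called falling without days 7 and 8, and 109 with reads scaled to the miRNA reads of each library, which takes the share out and moved slopes by a median of 0.13. Together these were 118 transcripts, for which the low share is excluded as the whole source of the call. The other 32 stay open, with a median slope under that scaling of -0.12 against -0.34 as deposited for the 31 miRNAs among them, and for them the low share cannot be told apart from a fall. Rescaling by median ratios kept 146 calls and quantile normalization 132, but median ratios raised MEF with day 7 and moved slopes by a median of only -0.002, and no biological explanation of the low share was tested.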
